A study of Mus musculus with 384 samples.

How the data were processed

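Liver RNA of 192 Diversity Outbred mice, an outbred stock descended from several inbred founder strains, was sequenced with single-end reads of 100 bp. Per the labels, the mice were 26 weeks old and had eaten chow (6% fat by weight) or a high fat diet (22% fat by weight) since weaning. Sex, diet, coat colour and an outbreeding generation label (G11L1 or G11L2) were given for each mouse, and no label explained what L1 and L2 stand for. The 384 sequenced samples were 2 technical repeats per mouse, randomly assigned to lanes, and the deposited table gave a single column to each mouse, so the mouse was the replicate.

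The authors deposited a table of 21454 genes by 192 mice whose values were a signal normalized to the upper quartile of each mouse, as the title of the table states and its low values show. The submitters' processing notes named CASAVA 1.8.0 and the builds GRCm38 and mm10. The aligner, the counting tool and the gene annotation were not given in the sources used here. Gene IDs were matched to GENCODE M21, which is on GRCm38: 21022 IDs had an entry, 432 had none, and 2 IDs shared a symbol. Coordinates below come from that annotation and are counted from 1. No column of other samples was left over.

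Depth was read from the low values, where 1 read has a fixed value in each mouse. Of the values up to 100 reads, 77.0% to 82.4% per mouse (median 79.8%) lay within 0.1 of a whole read, so whole reads were not recovered and no count test was run. By this estimate the mice had 9.79 to 17.9 M reads (megareads, median 14.2 M). Sampling noise of single reads was therefore not modelled, and precision rested on the number of mice.

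Genes were kept when the value was above 0 in at least 46 mice and the mean reached the pseudocount, which left 14602 genes, 14434 of them with a symbol. The values were tested as log2(value + 0.0629). The pseudocount was 1/100 of 6.29, the median upper quartile of the values above 0, and equals about 3.99 reads of the median mouse. A log2 change or fold is on this scale and understates the change of low genes. limma 3.58.1 in R 4.3.3 fitted 4 group means (sex by diet) with the generation label as a covariate and a mean-variance trend. Contrasts were the sex difference averaged over diets, the diet difference averaged over sexes, the diet difference in each sex, the difference between those 2 effects (interaction), and the generation label. A second fit added coat colour in the 186 agouti, black and white mice. It contrasted white with the mean of agouti and black, and black with agouti. Spread between mice was tested in the same way on the absolute deviation of each log2 value from the median of its group. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the tested genes, and a gene was called when the adjusted p was under 0.05. Log2 changes are given ± SE from limma and group values as mean ± SD over mice.

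A set of 37 gene lists (pathways, cell types and gene families of liver, with markers of neighbouring tissues) was fixed before the data were examined, as were the comparisons, tests, most of the alternatives and the rule for naming genes. Lists with at least 3 tested members (35) were tested with limma's camera and an estimated correlation between genes, adjusted over the 35 lists. This test sets the members of a list against all other genes, so its direction is relative to them. The median log2 change of all genes was 0.071 for sex and -0.067 for diet, so a list's own median can have the opposite sign. The X and Y lists, the male-biased, female-biased and major urinary protein lists rest on general knowledge and not on these samples. The naming rule took, for sex and diet, the 12 genes with the largest log2 change in each direction among called genes with a symbol and a mean of at least 10 pseudocounts in the higher group, passing over predicted genes and pseudogenes. For the interaction it took 6 in each direction. For generation, coat and spread it took the 6 smallest p-values in each direction, within each list up to 4 members with the smallest p, and finally the 10 genes with the largest residual SD. Some genes so chosen are not reported here, while counts include them.

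Alternatives were a pseudocount 10 times larger or smaller, no filter, a filter at 10 pseudocounts, median-of-ratios rescaling, quantile normalization, rank-based normal scores, array weights, robust moderation, no generation covariate, each generation label alone, a fold of at least 1.5, the mouse number as a replicate block, camera with its preset correlation, and limma's fry. Added after seeing the data were fits without 11 mice with pancreas transcripts, without the 10 mice least alike the others, and without 1 female lacking Xist. Upper-quartile values do not remove a shift common to most genes, so directions of small changes are given with the rescaled counts beside them.

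Reads shared between copies were estimated for 246 genes (those the rule named and the list members shown for sex) as the percentage of 50-base words of their transcripts found in another gene. For 24 genes it was over 50%, and their values are uncertain because the counting of such reads was not given. Strand use was not given either, so a gene and an antisense partner cannot be told apart.

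The tests given here were run on simulated values for the 14602 genes, with 200 genes changed. The white coat contrast, diet within a sex, and the list tests for sex and the interaction were not simulated. For diet, limma called 66.2% of changes of 0.2, 93.8% of 0.5 and 98.5% of 1 on the log2 scale, with 7 calls among unchanged genes. For sex the shares were 64.4%, 95.6% and 96.6% (7 such calls). For the interaction they were 18.9%, 74.3% and 92.9% (8 such calls). For generation they were 63.9%, 84.4% and 98.7% (9 such calls), and for black against agouti coat 47.8%, 85.5% and 94.7% (8 such calls). Planted differences in spread were recovered for 99.5% of genes by diet and 100% by sex, with 13 and 11 such calls. Their size is not given here, and the shares need not hold for genes near the pseudocount. For diet, 2 of 2 planted lists (cholesterol and interferon genes) were called and 0 of the others. The simulated genes varied independently, while the estimated correlation in the real data was 0.664 for cholesterol and 0.604 for interferon genes. The simulation therefore does not show how often lists of correlated genes are called or missed. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and data.table (version 1.17.8), and plots drawn with matplotlib 3.10.9.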

Results

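Liver RNA was measured in 192 outbred mice to follow how sex and diet set transcript levels. There were 50 females and 48 males on chow, and 48 females and 46 males on the high fat diet. The generation labels G11L1 (97 mice) and G11L2 (95 mice) were spread over all 4 groups, with 25 and 25 chow females, 24 and 24 high fat females, 23 and 25 chow males, and 25 and 21 high fat males. Coats were agouti in 131 mice, black in 30, white in 25, buff in 3, agouti with a blaze in 2 and red in 1.

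Estimated depth was alike in the 4 groups. Medians were 14.3 and 13.9 M reads in chow and high fat females and 14.6 and 13.8 M in males. Mean median-of-ratios factors were less alike, at 0.993 and 0.961 in females and 1.08 and 1.00 in males. Between 16076 and 17856 genes had a value above 0 in a mouse. The 10 largest genes took 15.3% to 31.4% of the summed signal of a mouse. Major urinary protein genes, which encode pheromone carriers secreted by the liver, took 11.4 ± 4.53% of it in chow males and 11.3 ± 5.28% in high fat males. In females their share was 2.11 ± 1.15% on chow and 1.29 ± 1.47% on the high fat diet. Haemoglobin transcripts made up 0.00119% to 0.295%.

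The first comparison asked which liver transcripts differ between males and females. Cytochromes P450, sulfotransferases and major urinary proteins were among the genes with the largest differences. Cyp4a12a, a fatty acid hydroxylase (ENSMUSG00000066071, chromosome 4, 115299046 to 115332815), had a signal of 225 ± 64.8 in chow males and 2.99 ± 7.87 in chow females, and was 211-fold higher in males (7.72 ± 0.17, adjusted p = 9.13e-103, 94 males and 98 females). Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), was 228-fold lower in males (-7.83 ± 0.11, adjusted p = 1.65e-134). limma called 9998 of 14602 genes, 6573 higher in males and 3425 higher in females, and 1074 of them differed at least 1.5-fold (552 higher and 522 lower in males). The share of calls higher in males was 65.7% with the deposited scaling, 47.5% after median-of-ratios rescaling and 53.3% after quantile normalization. Within the generation labels, 8312 genes were called in G11L1 mice and 8044 in G11L2 mice.

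Among the genes highest in males, Mup21 (6.68 ± 0.19), Mup20 (6.24 ± 0.19), Mup7 (5.34 ± 0.17) and Mup1 (5.00 ± 0.22) belong to the major urinary proteins. Mup20, the male pheromone darcin, had a signal of 313 ± 306 in chow males, 618 ± 728 in high fat males and 3.24 ± 2.22 in chow females. Hsd3b5, a hydroxysteroid dehydrogenase (6.40 ± 0.23), Cyp4a12b (5.66 ± 0.31), Cyp2d9, a steroid hydroxylase (5.34 ± 0.16), and Selenbp2, a selenium-binding protein (5.34 ± 0.26), followed. Moxd1 (4.95 ± 0.38), the calpain protease gene Capn8 (4.86 ± 0.16) and the serpin gene Serpina1e (4.78 ± 0.31) completed the 12 genes named on the male side. All 12 had an adjusted p of 2.13e-26 or smaller. Mup7 shared 86.7% of its sequence words with other genes, Mup1 61.6% and Mup20 50.5%, so their single values are uncertain.

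On the female side stood Cyp3a41b (-8.17 ± 0.28, adjusted p = 1.23e-70), Cyp3a41a (-7.55 ± 0.14), Cyp3a16 (-7.11 ± 0.17) and Cyp3a44 (-6.40 ± 0.17), all cytochromes P450 of the drug- and steroid-oxidizing 3A subfamily. The hydroxysteroid sulfotransferases Sult2a1 (-7.17 ± 0.20), Sult2a2 (-6.87 ± 0.23), Sult2a3 (-6.59 ± 0.20) and Sult2a5 (-6.46 ± 0.13) were lower in males as well. Sult2a1 had a signal of 102 ± 51.8 in chow females and 1.20 ± 3.81 in chow males. A1bg, a plasma glycoprotein (-6.90 ± 0.25), Cyp2c69 (-6.60 ± 0.22) and Cyp2b13 (-5.60 ± 0.26) completed that side. Shared sequence words reached 98.6% for Cyp3a41a, 93.5% for Cyp3a41b, 62.1% for Sult2a2 and 54.3% for Cyp2c69.

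Lists of sex-biased liver genes drawn from general knowledge moved as whole groups. All 17 tested male-biased genes were higher in males (17 adjusted over the list alone, set-test adjusted p = 1e-05 with an estimated correlation), among them Elovl3, a fatty acid elongase (4.24 ± 0.13), and Susd4 (4.76 ± 0.15). All 24 tested female-biased genes were lower in males (24 adjusted over the list alone, set-test adjusted p = 5.4e-10 with an estimated correlation), with the transcription factor gene Cux2 at -5.49 ± 0.12. Of 20 major urinary protein genes, 19 were higher in males and 1 did not pass the test (19 adjusted over the list alone, set-test adjusted p = 0.00347 with an estimated correlation). The 5 X-inactivation and escape genes were lower in males (5 adjusted over the list alone, set-test adjusted p = 0.00131 with an estimated correlation), at -0.51 ± 0.031 for Kdm6a, -0.47 ± 0.024 for Eif2s3x, -0.17 ± 0.029 for Ddx3x and -0.16 ± 0.029 for Kdm5c. No member of the Y-linked list was tested. These 4 lists were the only ones of 35 past the set test for sex with the deposited scaling and an estimated correlation.

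No list of lipid pathways passed the set test for sex with the deposited scaling. Cholesterol biosynthesis and uptake genes were lower in males in 17 of 25 cases (17 adjusted over the list alone, set-test adjusted p = 0.613 with an estimated correlation). Among them were Srebf2 (-0.30 ± 0.037), Tm7sf2 (-0.37 ± 0.061) and Fdft1 (-0.43 ± 0.073). Fatty acid synthesis genes were lower in 12, higher in 3 and not past the test in 3 (15 adjusted over the list alone, set-test adjusted p = 0.567 with an estimated correlation). Members included Fads1 (-0.84 ± 0.063), Fads2 (-0.68 ± 0.067) and Acacb (-0.95 ± 0.12) among the lower and the triglyceride hydrolase gene Pnpla3 at -2.58 ± 0.25. Targets of PPAR alpha and other fatty acid oxidation genes were lower in 20 of 30 and higher in 4 (24 adjusted over the list alone, set-test adjusted p = 0.298 with an estimated correlation). Examples were Cyp4a10 (-2.33 ± 0.17), Vnn1 (-2.26 ± 0.16), Acot2 (-1.62 ± 0.098) and Acot1 (-1.69 ± 0.13). Lipid droplet and PPAR gamma targets were higher in 6 and lower in 4, but 6 higher and 9 lower after median-of-ratios rescaling and 5 and 8 after quantile normalization (10 adjusted over the list alone, set-test adjusted p = 0.774 with an estimated correlation). Cd36, a fatty acid translocase, was at -1.50 ± 0.11 and Fitm1 at 0.86 ± 0.14. Lipoprotein genes were higher in 4 and lower in 5 (9 adjusted over the list alone, set-test adjusted p = 0.765 with an estimated correlation), with Pltp at -1.05 ± 0.10 and the HDL receptor gene Scarb1 at 0.30 ± 0.048.

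Bile acid genes were higher in males in 8 and lower in 4 of 17 (13 adjusted over the list alone, set-test adjusted p = 0.872 with an estimated correlation), and the list was 8 higher and 7 lower after median-of-ratios rescaling and 6 and 7 after quantile normalization. Cyp7b1, an oxysterol hydroxylase, was at 3.00 ± 0.17 and Cyp27a1 at 0.47 ± 0.047. Gluconeogenesis and fasting genes were higher in 2 and lower in 5 of 13 (7 adjusted over the list alone, set-test adjusted p = 0.613 with an estimated correlation). They included Igfbp1 (-1.09 ± 0.16), Irs2 (-0.71 ± 0.09) and Ppargc1a (-0.49 ± 0.061). Urea cycle and amino acid genes were split 8 higher and 7 lower, and 2 higher and 8 lower after median-of-ratios rescaling and 2 and 12 after quantile normalization (15 adjusted over the list alone, set-test adjusted p = 0.872 with an estimated correlation). Their median was 0.047 and mean 0.005 while the set test pointed down, and Tdo2 stood at 0.81 ± 0.05 and Hpd at -0.42 ± 0.053. Xenobiotic metabolism genes were higher in 7 and lower in 8 of 20 (15 adjusted over the list alone, set-test adjusted p = 0.567 with an estimated correlation). Their median was 0.028, and -0.06 after median-of-ratios rescaling, while mean (-0.06) and set test pointed down, and Gstt3 (-1.82 ± 0.089), Nr1i3 (-0.95 ± 0.089) and Por (-0.83 ± 0.084) were lower in males. NRF2 targets were higher in 7 and lower in 5 of 14 (13 adjusted over the list alone, set-test adjusted p = 0.891 with an estimated correlation). Among them were Gclc (0.50 ± 0.05) and Nqo1 (-0.97 ± 0.089). Unfolded protein and integrated stress response genes were higher in 14 and lower in 2 of 19 (17 adjusted over the list alone, set-test adjusted p = 0.189 with an estimated correlation), including the chaperone genes Sdf2l1 (1.36 ± 0.094), Hyou1 (1.09 ± 0.07) and Hspa5 (0.81 ± 0.057).

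No list of immune or other non-hepatocyte markers passed the set test for sex with the deposited scaling. Lower in males were 16 of 19 T, NK and B cell markers (17 adjusted over the list alone, set-test adjusted p = 0.0676 with an estimated correlation). Examples were Cd3g (-0.71 ± 0.07), Lck (-0.67 ± 0.067) and Nkg7 (-0.62 ± 0.075). So were 14 of 15 Kupffer cell and macrophage markers (15 adjusted over the list alone, set-test adjusted p = 0.298 with an estimated correlation). Examples were Vsig4 (-0.74 ± 0.074), Adgre1 (-0.64 ± 0.086) and Csf1r (-0.60 ± 0.067). All 7 MHC class II genes were lower (7 adjusted over the list alone, set-test adjusted p = 0.298 with an estimated correlation). They included Ciita (-0.74 ± 0.099) and H2-Aa (-0.71 ± 0.10). Sinusoidal endothelial markers were lower in 12 of 14 (12 adjusted over the list alone, set-test adjusted p = 0.189 with an estimated correlation). Among them were Oit3 (-0.30 ± 0.037) and Kdr (-0.20 ± 0.033). Interferon response genes were lower in 10 and higher in 3 of 21 (13 adjusted over the list alone, set-test adjusted p = 0.692 with an estimated correlation). Members included Gbp2 (-1.22 ± 0.094) and Gbp3 (-1.27 ± 0.11). Of 8 neutrophil markers 5 were lower (5 adjusted over the list alone, set-test adjusted p = 0.613 with an estimated correlation). Examples were Csf3r (-0.34 ± 0.08) and Mmp9 (-0.41 ± 0.096). Monocyte-derived and lipid-associated macrophage markers were lower in 4, higher in 1 and not past the test in 8 (5 adjusted over the list alone, set-test adjusted p = 0.774 with an estimated correlation). They included Itgam (-0.45 ± 0.11) and Spp1 (0.54 ± 0.12).

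Erythroid genes were higher in 2 and lower in 5 of 8 (7 adjusted over the list alone, set-test adjusted p = 0.862 with an estimated correlation), with Alas2 at 2.49 ± 0.17 and Slc4a1 at -0.71 ± 0.13. Stellate cell and fibrosis markers were higher in 6 and lower in 5, but 3 higher and 7 lower after median-of-ratios rescaling and 6 and 7 after quantile normalization (11 adjusted over the list alone, set-test adjusted p = 0.872 with an estimated correlation), and Col4a2 was at 0.59 ± 0.062. Bile duct markers were higher in 1 and lower in 3 of 10 (4 adjusted over the list alone, set-test adjusted p = 0.809 with an estimated correlation), with a median of 0.042, a mean of -0.041, a set test pointing down and Sox9 (0.97 ± 0.084) and Krt23 (-1.48 ± 0.21). Neither the 9 pancreas markers (0 adjusted over the list alone, set-test adjusted p = 0.912 with an estimated correlation) nor the 4 skeletal muscle markers (0 adjusted over the list alone, set-test adjusted p = 0.809 with an estimated correlation) held a called gene, the nearest being Ctrb1 (0.28 ± 0.29, adjusted p = 0.392) and Tnnt3 (-0.28 ± 0.14, adjusted p = 0.0608). The pancreas median was 0.19, while the set test pointed down relative to other genes. Of the adipose list only Cidea (0.99 ± 0.19) and Fabp4 (0.26 ± 0.11) were tested, both higher in males (2 adjusted over the list alone), and 2 members are too few for a set test. Fabp4 lost its call after median-of-ratios rescaling (0.17, adjusted p = 0.166), with array weights (adjusted p = 0.0562), in G11L1 and in G11L2 mice alone (0.279 and 0.0924) and without the 10 least alike mice (0.21).

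Acute phase genes were higher in males in 12 and lower in 4 of 22 (16 adjusted over the list alone, set-test adjusted p = 0.953 with an estimated correlation), and 10 higher and 7 lower after median-of-ratios rescaling and 5 and 9 after quantile normalization. Their median was 0.29, their mean -0.043 and the set test pointed down, with the metallothionein genes Mt1 (-2.07 ± 0.25) and Mt2 (-2.13 ± 0.29) lower. Clock genes were higher in 6 and lower in 5 (12 adjusted over the list alone, set-test adjusted p = 0.872 with an estimated correlation), and 6 higher and 7 lower after median-of-ratios rescaling and 6 and 7 after quantile normalization. Their median was -0.019 and mean 0.078, with a set test pointing down and Clock (0.65 ± 0.056), Bhlhe41 (0.99 ± 0.13) and Per3 (-0.87 ± 0.11). Cell cycle genes were higher in 6 and lower in 2 of 19 (4 adjusted over the list alone, set-test adjusted p = 0.872 with an estimated correlation), and 1 higher and 3 lower after median-of-ratios rescaling and 10 and 3 after quantile normalization. Their median was 0.18 and mean 0.022, while the set test pointed down relative to other genes, and the cyclin gene Ccnd1 was at -1.60 ± 0.12. Central hepatocyte genes were lower in 9 and higher in 3 of 15 (12 adjusted over the list alone, set-test adjusted p = 0.765 with an estimated correlation). Among them were Oat (-0.52 ± 0.10) and Cyp1a2 (0.36 ± 0.072). Periportal genes were higher in 7 and lower in 4 (11 adjusted over the list alone, set-test adjusted p = 0.872 with an estimated correlation), and 4 higher and 5 lower after median-of-ratios rescaling and 4 and 8 after quantile normalization. Their median was 0.07 and mean 0.11, while the set test pointed down relative to other genes, with Cyp2f2 (0.98 ± 0.075) and Ctsc (-0.87 ± 0.058).

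Insulin and growth hormone signalling genes were lower in 13 and higher in 3 of 21 (16 adjusted over the list alone, set-test adjusted p = 0.108 with an estimated correlation), with the prolactin receptor gene Prlr at -1.83 ± 0.081, the leptin receptor gene Lepr at -1.45 ± 0.12 and Esr1, the oestrogen receptor alpha gene, at -1.20 ± 0.082. Ribosomal protein genes were higher in males in 26 of 39 (26 adjusted over the list alone, set-test adjusted p = 0.826 with an estimated correlation) and 10 higher and 1 lower after median-of-ratios rescaling and 11 and 2 after quantile normalization, with Rplp0 at 0.26 ± 0.027. Oxidative phosphorylation genes were higher in 24 and lower in 1 of 38 (25 adjusted over the list alone, set-test adjusted p = 0.872 with an estimated correlation), a balance that turned to 7 higher and 8 lower after median-of-ratios rescaling and 5 and 10 after quantile normalization, and Ndufa4 stood at 0.26 ± 0.028.

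The second comparison asked how the high fat diet changed the liver transcriptome. Lipid droplet genes and markers of lipid-associated macrophages rose as lists, and each of the 25 tested cholesterol genes fell, though their list did not pass the set test (adjusted p = 0.0876 with an estimated correlation). Scd1, the stearoyl-CoA desaturase (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), rose 3.32-fold (1.73 ± 0.18, adjusted p = 1.17e-16, 94 high fat and 98 chow mice). Its median signal went from 746 to 3149 in females and from 739 to 1828 in males. Idi1, an isomerase of the sterol pathway (ENSMUSG00000058258, chromosome 13, 8885501 to 8892451), fell 3.62-fold (-1.86 ± 0.11, adjusted p = 3.49e-34). limma called 8310 of 14602 genes, 2185 higher and 6125 lower on the high fat diet, and at least 1.5-fold changes were 231 higher and 193 lower. The share of calls that were higher was 26.3% with the deposited scaling, 52.1% after median-of-ratios rescaling (3634 higher and 3338 lower) and 45.4% after quantile normalization. Within the generation labels, 5713 genes were called in G11L1 mice and 6338 in G11L2 mice.

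**Figure D1:**
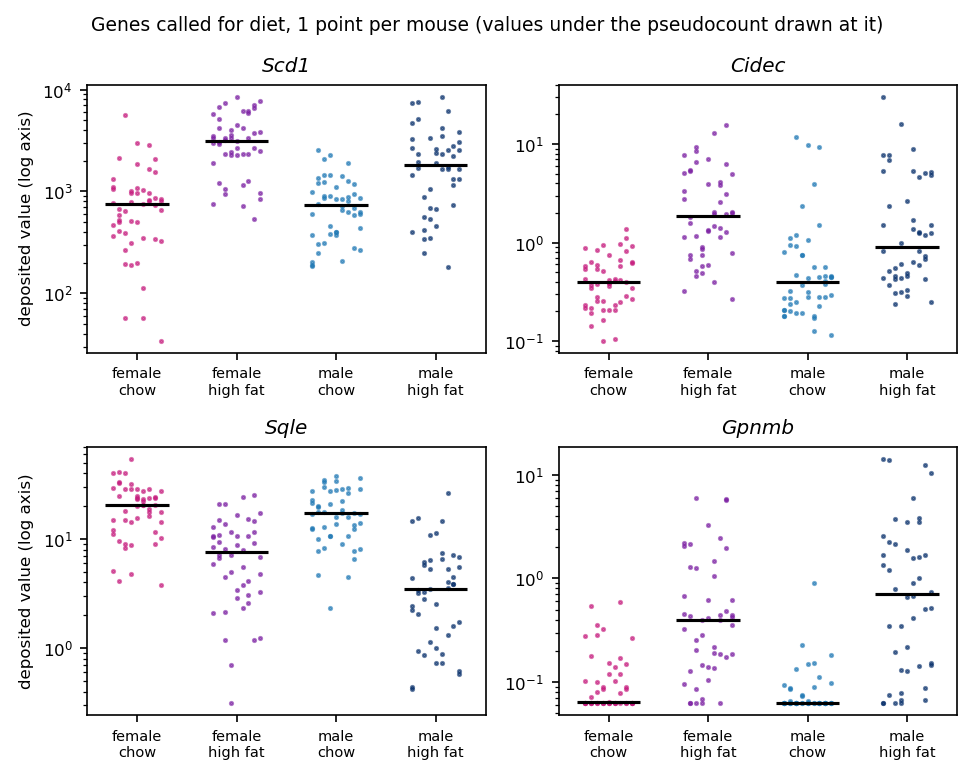
Signal of Scd1, Cidec, Sqle and Gpnmb in each of the 192 mice (points) by sex and diet, with the group median as a bar and a log axis on which values under the pseudocount are drawn at it. Median Cidec in chow and high fat mice was 0.395 and 1.88 in females and 0.393 and 0.905 in males, and median Sqle in males was 17.2 and 3.48.

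The largest rise was that of Ly6d, a cell surface antigen of the Ly6 family (ENSMUSG00000034634, chromosome 15, 74762056 to 74763620), from 0.329 ± 0.490 to 4.14 ± 4.53 in females and from 0.221 ± 0.423 to 2.93 ± 4.36 in males (3.07 ± 0.20, adjusted p = 1.07e-30). Gpnmb, a glycoprotein of lipid-loaded macrophages (2.28 ± 0.21, adjusted p = 1.26e-19), and Mmp12, macrophage elastase (1.85 ± 0.17), rose with it. So did genes of lipid handling: Mogat1, a monoacylglycerol acyltransferase (2.15 ± 0.17), Pnpla3 (1.79 ± 0.25), Pnpla5 (1.73 ± 0.18), the apolipoprotein gene Apoa4 (1.75 ± 0.16), Smpd3, a neutral sphingomyelinase (1.70 ± 0.16), and Cidec, a lipid droplet protein (1.68 ± 0.19). Gprc5b, an orphan receptor (1.94 ± 0.19), and Ifi27l2b, an interferon-inducible gene (1.61 ± 0.25, adjusted p = 7.7e-09), completed the 12.

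Sterol enzymes were 4 of the 12 genes that fell most. Besides Idi1 these were squalene epoxidase Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192, -1.93 ± 0.17, adjusted p = 1.97e-21), Msmo1 (-1.65 ± 0.11) and lanosterol demethylase Cyp51 (-1.64 ± 0.11). Sult5a1, a sulfotransferase, had the largest drop (-2.14 ± 0.26), and Tcf24 (-1.90 ± 0.24) was among the others. Enho, which encodes adropin (-1.67 ± 0.20), Cyp26a1, which clears retinoic acid (-1.57 ± 0.17), Serpina1e (-1.43 ± 0.31, adjusted p = 3.03e-05), Cyp2c69 (-1.42 ± 0.22) and Sult2a7 (-1.40 ± 0.29, adjusted p = 1.26e-05) also fell. Sult2a7 did not pass in G11L1 mice alone (-1.01, adjusted p = 0.0517, from 3.29e-07 to 0.0517 over its alternatives).

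As a group, lipid droplet and PPAR gamma targets rose: 13 of 18 were higher and none lower (13 adjusted over the list alone, set-test adjusted p = 0.0139 with an estimated correlation), among them Mogat1 (2.15 ± 0.17), Plin4 (1.14 ± 0.16) and Cd36 (0.93 ± 0.11). Monocyte-derived and lipid-associated macrophage markers rose in 10 of 13 and fell in none (10 adjusted over the list alone, set-test adjusted p = 0.013 with an estimated correlation). Members included Gpnmb (2.28 ± 0.21), Trem2 (1.25 ± 0.12) and Cd63 (0.95 ± 0.11). These were the 2 lists past the set test for diet. Cholesterol biosynthesis and uptake genes fell in 25 of 25 (25 adjusted over the list alone, set-test adjusted p = 0.0876 with an estimated correlation), with the regulator Srebf2 at -0.55 ± 0.037. That set p was 0.029 after median-of-ratios rescaling and ranged from 2.2e-22 to 0.169 over its alternatives. Fatty acid synthesis genes rose in 13, fell in 1 and did not pass in 4 (15 adjusted over the list alone, set-test adjusted p = 0.145 with an estimated correlation). An example beside Scd1 was Fads2 (0.78 ± 0.067). Fatty acid oxidation genes and PPAR alpha targets rose in 15 and fell in 2 of 30, and were 22 higher and 1 lower after median-of-ratios rescaling and 27 and 0 after quantile normalization (18 adjusted over the list alone, set-test adjusted p = 0.31 with an estimated correlation). Vnn1, a pantetheinase, was at 1.56 ± 0.16 and Acot2 at 0.68 ± 0.098. Lipoprotein genes rose in 3 and fell in 6 of 15 (10 adjusted over the list alone, set-test adjusted p = 0.736 with an estimated correlation), a balance that turned to 4 higher and 4 lower after median-of-ratios rescaling and 7 and 1 after quantile normalization. Their median was -0.084, while the mean (0.14) and set test pointed up, with Pltp (0.94 ± 0.10) and Apoc2 (0.81 ± 0.065).

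**Figure D2:**
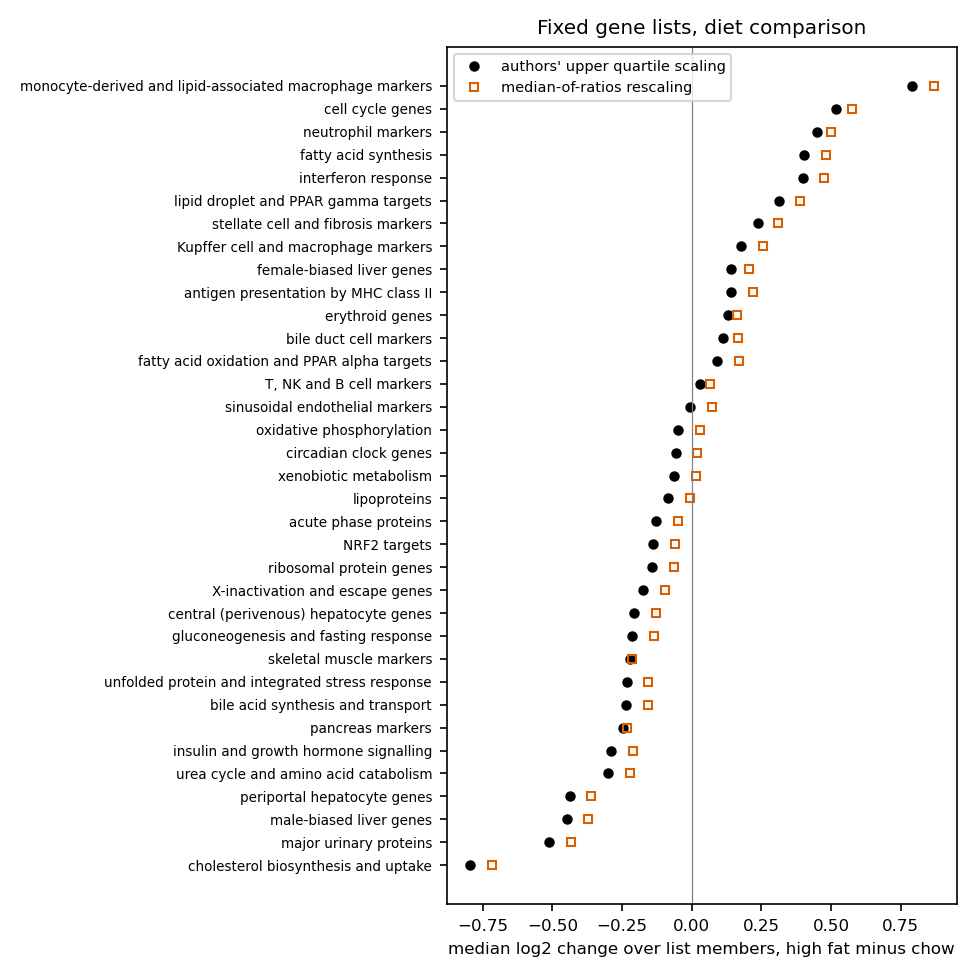
Median log2 change on the high fat diet of each gene list with at least 3 tested members, with the deposited scaling and after median-of-ratios rescaling. Cholesterol genes had the lowest median (-0.80, and -0.72 rescaled) and lipid-associated macrophage markers the highest (0.79, and 0.87 rescaled), while oxidative phosphorylation changed sign (-0.05, and 0.03 rescaled).

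No other list of hepatocyte functions passed the set test for diet with the deposited scaling. Urea cycle and amino acid genes fell in 20 of 22 (21 adjusted over the list alone, set-test adjusted p = 0.221 with an estimated correlation). They included Cth (-0.99 ± 0.074), Hal (-0.70 ± 0.07) and Agxt (-0.68 ± 0.06). Periportal hepatocyte genes fell in 13 and rose in 1 of 16 (15 adjusted over the list alone, set-test adjusted p = 0.14 with an estimated correlation), with Etnppl at -1.03 ± 0.12 and Pigr at -0.49 ± 0.052. Their set p was 0.029 after median-of-ratios rescaling and from 2.14e-21 to 0.275 over its alternatives. Central hepatocyte genes fell in 9 and rose in 1 of 15 (10 adjusted over the list alone, set-test adjusted p = 0.736 with an estimated correlation). Among them were Gstm1 (-0.41 ± 0.073) and Rgn (-0.26 ± 0.044). Bile acid genes fell in 12 of 17 (13 adjusted over the list alone, set-test adjusted p = 0.314 with an estimated correlation), such as the bile salt export pump gene Abcb11 (-0.48 ± 0.045). Gluconeogenesis and fasting genes fell in 7 and rose in 2, but were 2 higher and 5 lower after median-of-ratios rescaling and 3 and 2 after quantile normalization (10 adjusted over the list alone, set-test adjusted p = 0.97 with an estimated correlation), with G6pc, glucose-6-phosphatase, at -0.63 ± 0.12. Insulin and growth hormone signalling genes fell in 15 and rose in 1 of 21 (16 adjusted over the list alone, set-test adjusted p = 0.314 with an estimated correlation). Members included Prlr (-0.55 ± 0.081), Klb (-0.45 ± 0.057) and Stat5b (-0.34 ± 0.033). Xenobiotic metabolism genes fell in 7 and rose in 2 of 20 (9 adjusted over the list alone, set-test adjusted p = 0.97 with an estimated correlation). Their median of -0.063 became 0.015 after median-of-ratios rescaling, and Gsta2 (-1.10 ± 0.17), Cyp1a2 (-0.80 ± 0.072) and Ces2a (-0.61 ± 0.079) fell.

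NRF2 targets fell in 7 and rose in 2 of 14 (11 adjusted over the list alone, set-test adjusted p = 0.736 with an estimated correlation), and were 4 higher and 7 lower after median-of-ratios rescaling and 4 and 4 after quantile normalization, with Gsta4 (-0.51 ± 0.071) and G6pdx (0.42 ± 0.072). Unfolded protein and integrated stress response genes fell in 11 and rose in 4 of 19 (15 adjusted over the list alone, set-test adjusted p = 0.945 with an estimated correlation). Examples were Hyou1 (-0.42 ± 0.071) and Atf3 (0.89 ± 0.096). Acute phase genes fell in 8 and rose in 6, and were 6 higher and 6 lower after median-of-ratios rescaling and 6 and 5 after quantile normalization (14 adjusted over the list alone, set-test adjusted p = 0.975 with an estimated correlation). Their median was -0.13 against a mean of 0.041 and a set test pointing up, and complement C3 was at -0.53 ± 0.047. Clock genes rose in 5 and fell in 6 (11 adjusted over the list alone, set-test adjusted p = 0.839 with an estimated correlation), and were 6 higher and 4 lower after median-of-ratios rescaling and 7 and 4 after quantile normalization. Their median (-0.057) and mean (-0.025) lay below 0 while the set test pointed up relative to other genes. Members included Per3 (0.58 ± 0.11), Per2 (0.55 ± 0.11) and Nr1d1 (-0.43 ± 0.077). Cell cycle genes rose in 17 of 19 (17 adjusted over the list alone, set-test adjusted p = 0.0876 with an estimated correlation). They included Mki67 (0.74 ± 0.12), Cenpe (0.61 ± 0.092) and Mcm6 (0.60 ± 0.10). Ribosomal protein genes fell in 27 of 39 (27 adjusted over the list alone, set-test adjusted p = 0.601 with an estimated correlation), and were 0 higher and 16 lower after median-of-ratios rescaling and 0 and 3 after quantile normalization, with Rpsa at -0.25 ± 0.032. Oxidative phosphorylation genes fell in 13 and rose in 1 of 38 (13 adjusted over the list alone, set-test adjusted p = 0.975 with an estimated correlation), a balance that turned to 10 higher and 1 lower after median-of-ratios rescaling and 26 and 0 after quantile normalization, with Sdha at -0.15 ± 0.027.

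The other lists of non-hepatocyte markers did not pass the set test for diet with the deposited scaling. Interferon response genes rose in 18 of 21 (18 adjusted over the list alone, set-test adjusted p = 0.295 with an estimated correlation). Among them were Ifi44 (0.77 ± 0.16), Cxcl10 (0.73 ± 0.11) and Oas1a (0.70 ± 0.14). Kupffer cell and macrophage markers rose in 9 and fell in 1 of 15 (10 adjusted over the list alone, set-test adjusted p = 0.601 with an estimated correlation). Members included Cd68 (0.39 ± 0.07) and Cd163 (-0.60 ± 0.12). Neutrophil markers rose in 6 and fell in 1 of 8 (7 adjusted over the list alone, set-test adjusted p = 0.221 with an estimated correlation). Examples were S100a9 (0.80 ± 0.15) and S100a8 (0.68 ± 0.13). Stellate cell and fibrosis markers rose in 10 and fell in 1 of 18 (12 adjusted over the list alone, set-test adjusted p = 0.0876 with an estimated correlation), including the collagen genes Col1a1 (1.04 ± 0.11), Col3a1 (0.83 ± 0.096) and Col1a2 (0.76 ± 0.091). Bile duct markers rose in 5 of 10 (5 adjusted over the list alone, set-test adjusted p = 0.0876 with an estimated correlation). They included Krt23 (0.93 ± 0.21) and Cd24a (0.46 ± 0.083). Of 7 MHC class II genes 3 rose (3 adjusted over the list alone, set-test adjusted p = 0.601 with an estimated correlation). Among them were Ciita (0.31 ± 0.099) and H2-DMb1 (0.24 ± 0.095). H2-DMb1 passed in neither generation label alone (adjusted p = 0.252 and 0.0706) nor without the 10 least alike mice (0.0522), and Ciita did not pass in G11L1 mice (0.15, adjusted p = 0.351). T, NK and B cell markers rose in 3 and fell in 2 of 19 (3 adjusted over the list alone, set-test adjusted p = 0.645 with an estimated correlation), and were 5 higher and 2 lower after median-of-ratios rescaling and 1 and 2 after quantile normalization, with Jchain at -0.57 ± 0.14 and Cd52 at 0.28 ± 0.095.

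Sinusoidal endothelial markers rose in 4 and fell in 4 of 14 (8 adjusted over the list alone, set-test adjusted p = 0.736 with an estimated correlation), and were 6 higher and 1 lower after median-of-ratios rescaling and 7 and 0 after quantile normalization. Their median was -0.005 against a mean of 0.044 and a set test pointing up, with Lyve1 (0.66 ± 0.13), Vwf (0.32 ± 0.042) and Ptprb (-0.18 ± 0.039). Of 8 erythroid genes 2 fell (1 adjusted over the list alone, set-test adjusted p = 0.736 with an estimated correlation), namely Alas2 (-0.40 ± 0.17) and Bpgm (-0.12 ± 0.038), and neither passed after median-of-ratios rescaling. Both tested adipose markers rose, Cidea (0.95 ± 0.19) and Fabp4 (0.62 ± 0.11), with 2 adjusted over the list alone. No pancreas marker of 9 was called (0 adjusted over the list alone, set-test adjusted p = 0.97 with an estimated correlation), and the median of -0.25 went against a set test pointing up, with Cela2a at -0.51 ± 0.26 (adjusted p = 0.0879). Of 4 skeletal muscle markers 1 fell (1 adjusted over the list alone, set-test adjusted p = 0.97 with an estimated correlation), namely Mylpf (-0.25 ± 0.10), which did not pass after median-of-ratios rescaling. Genes of the sex lists moved too. Male-biased genes fell in 11 and rose in 1 of 17 (13 adjusted over the list alone, set-test adjusted p = 0.736 with an estimated correlation). Members included Egfr (-0.99 ± 0.14), Cyp7b1 (-0.95 ± 0.17) and Slco1a1 (-0.88 ± 0.23). Female-biased genes rose in 9 and fell in 7 of 24 (16 adjusted over the list alone, set-test adjusted p = 0.736 with an estimated correlation), with a median of 0.14, a mean of -0.036 and a set test pointing up, and with Ntrk2 (1.48 ± 0.25) and Cyp3a44 (-1.20 ± 0.17). Major urinary protein genes fell in 8 and rose in 1 of 20 (9 adjusted over the list alone, set-test adjusted p = 0.97 with an estimated correlation). Examples were Mup1 (-1.16 ± 0.22) and Mup7 (-0.89 ± 0.17). X-inactivation and escape genes fell in 4 of 5 (4 adjusted over the list alone, set-test adjusted p = 0.31 with an estimated correlation), with Ddx3x at -0.30 ± 0.029, and Xist was at 0.005 ± 0.11 (adjusted p = 0.976). In G11L1 mice alone Krt23, Cd52, Slco1a1 and Mylpf did not pass for diet (adjusted p = 0.17, 0.147, 0.118 and 0.446). After quantile normalization Rgn, Ptprb and Sdha did not (0.149, 0.13 and 0.589), and Alas2 and Bpgm passed neither after it nor within a generation label.

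Diet effects were next compared between the sexes, within each sex and by their difference. Single genes answered the high fat diet by different amounts in males and females. Sult1e1, the oestrogen sulfotransferase (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), rose in males (2.80 ± 0.38, adjusted p = 2.37e-10) and did not pass in females (-0.78 ± 0.37, adjusted p = 0.0922), and the difference of the effects was 3.58 ± 0.53 (adjusted p = 2.35e-07). Cyp3a11, a drug-metabolizing cytochrome P450 (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964), changed by 1.43 ± 0.20 in females and -0.995 ± 0.20 in males, with both effects past the test (adjusted p = 7.32e-10 and 1.08e-05) and a difference of -2.43 ± 0.28 (adjusted p = 2.67e-11). Diet was called for 4860 genes in females (1460 higher and 3400 lower) and 7479 in males (1669 higher and 5810 lower). At least 1.5-fold changes were 473 in females (248 and 225) and 538 in males (319 and 219). After median-of-ratios rescaling the split was 2194 higher and 2142 lower in females, and 2828 and 2453 in males. Within G11L1 and G11L2 mice 2348 and 2432 genes were called in females and 5011 and 4930 in males.

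Across the 14602 genes the 2 diet effects correlated at Pearson's r = 0.623 and Spearman's rho = 0.622, where genes are not independent replicates. Genes called in both sexes numbered 3515, of which 3437 moved in the same direction and 78 in opposite directions. The interaction was called for 1223 genes, 213 with a more positive effect in males and 1010 with a more negative one, and 188 differed at least 1.5-fold (94 and 94). After median-of-ratios rescaling it was called for 617 genes (311 and 306), and 510 of the 1223 calls were shared. The positive share was 17.4% with the deposited scaling, 50.4% after that rescaling and 42.5% after quantile normalization (633 calls). Of the 1223 genes, 716 were called for diet in males alone, 268 in females alone, 141 in both in the same direction, 78 in both in opposite directions and 20 in neither. Within G11L1 mice 546 genes were called and within G11L2 mice 54.

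**Figure D3:**
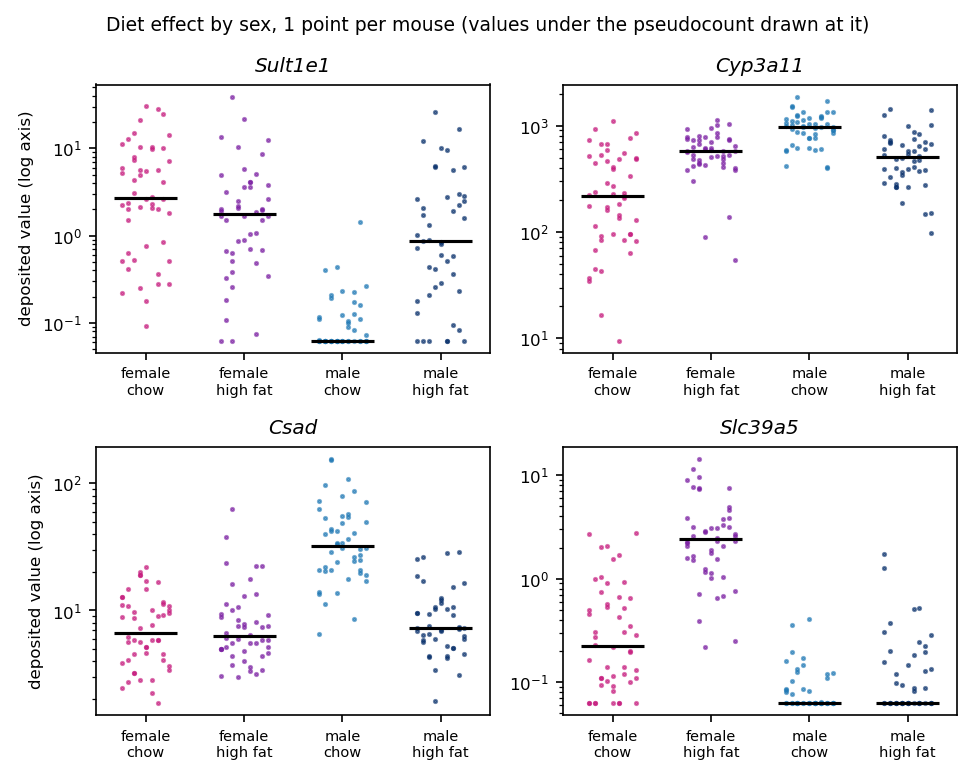
Signal of Sult1e1, Cyp3a11, Csad and Slc39a5 in each of the 192 mice (points) by sex and diet, with the group median as a bar and a log axis on which values under the pseudocount are drawn at it. Median Cyp3a11 went from 219.7 to 575 in females and from 977 to 505 in males, and median Csad from 6.70 to 6.25 and from 32.2 to 7.27.

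Among genes with a more positive effect in males, Sult5a1 changed by -3.38 ± 0.36 in females and -0.89 ± 0.36 in males and Sult2a7 by -2.51 ± 0.41 in females and -0.30 ± 0.42 in males. A1bg changed by -2.20 ± 0.34 in females and 0.013 ± 0.35 in males, and Ptgds, a prostaglandin D synthase, by -2.22 ± 0.20 in females and -0.31 ± 0.20 in males. Their interaction adjusted p-values were 0.000469, 0.00743, 0.00124 and 2.35e-07. On the other side, the zinc transporter gene Slc39a5 changed by 2.77 ± 0.24 in females and 0.36 ± 0.24 in males and Csad, a decarboxylase of taurine synthesis, by 0.091 ± 0.19 in females and -2.03 ± 0.19 in males (interaction adjusted p = 7.4e-08 and 1.22e-09). Obp2a, an odorant-binding protein gene, changed by 0.14 ± 0.37 in females and -1.69 ± 0.38 in males, Gprc5b by 2.81 ± 0.27 in females and 1.06 ± 0.28 in males and the acid phosphatase gene Acpp by 1.91 ± 0.35 in females and 0.28 ± 0.35 in males (interaction adjusted p = 0.0176, 0.00115 and 0.0219). The effect in males did not pass for Sult2a7, A1bg, Ptgds, Slc39a5 and Acpp, nor that in females for Csad and Obp2a (adjusted p of 0.187 or more). Obp2a had means of 0.0109 and 0.0209 in females, under the pseudocount, where a drop cannot be seen, so its interaction does not compare 2 measured responses. For the interaction, Ptgds, Cyp3a11, Slc39a5 and Csad passed within both generation labels. Sult2a7, Obp2a and Acpp passed in neither, Sult5a1 and Gprc5b not in G11L1 mice (adjusted p = 0.079 and 0.215), and Sult1e1 and A1bg not in G11L2 mice (0.0738 and 0.225). With rank-based normal scores Sult2a7 and Acpp did not pass (0.0578 and 0.0914).

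Of the 35 lists, the female-biased genes alone passed the set test for the interaction, with 6 of 24 more positive in males (7 adjusted over the list alone, set-test adjusted p = 0.0359 with an estimated correlation). That p was 0.149 after median-of-ratios rescaling and 0.588 in G11L2 mice, and ranged from 1.01e-11 to 0.588 over its alternatives. Its member Atp6v0d2, a vacuolar ATPase subunit gene, was at 1.25 ± 0.30 (adjusted p = 0.00265), and at 0.63 (adjusted p = 0.556) in G11L2 mice alone. Fatty acid oxidation genes and PPAR alpha targets were more negative in males in 19 of 30 (20 adjusted over the list alone, set-test adjusted p = 0.266 with an estimated correlation), and in 9 after median-of-ratios rescaling, with Crat (-1.01 ± 0.16), Acot1 (-1.58 ± 0.26) and Hadhb (-0.30 ± 0.063). In females 18 of these genes rose and none fell, and in males 5 rose and 7 fell (8 and 2 after median-of-ratios rescaling). Acot1 and Hadhb did not pass in G11L2 mice alone (adjusted p = 0.0568 and 0.275).

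Mice with the 2 generation labels differed in few genes. Hamp, which encodes the iron hormone hepcidin (ENSMUSG00000050440, chromosome 7, 30942368 to 30944032), was 1.77-fold higher in G11L2 mice (0.83 ± 0.12, adjusted p = 1.68e-06, 95 and 97 mice). The transcription factor gene Twist1 (-0.62 ± 0.088, adjusted p = 4.88e-07) and Slc4a1, the anion exchanger of red cells (-0.67 ± 0.13), were lower, and Slc4a1 lost its call with 10 times the pseudocount (adjusted p = 0.0547). limma called 137 genes (58 higher and 79 lower in G11L2), 8 of them at least 1.5-fold. After median-of-ratios rescaling 262 were called (155 and 107), which moved the higher share from 42.3% to 59.2%, and it was 49.6% after quantile normalization. Higher in G11L2 mice were also the predicted antisense gene Gm4673 (0.39 ± 0.06), LTO1 (0.22 ± 0.036), Adgrd1 (0.36 ± 0.071), Myl6 (0.12 ± 0.024) and Tmem258 (0.15 ± 0.032). Lower were Sema6c (-0.32 ± 0.058), Chst15 (-0.17 ± 0.034), Kdr (-0.16 ± 0.033) and Sntg2 (-0.34 ± 0.072). Without the 11 mice that carried pancreas transcripts 112 genes were called.

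Coat colour was compared as an inherited trait recorded for each mouse. Black against agouti coats (30 and 131 mice), which the nonagouti gene separates, went with large opposite shifts in Ahcy and a gene similar to it. Ahcy, which hydrolyses S-adenosylhomocysteine (ENSMUSG00000027597, chromosome 2, 155059310 to 155074497), had a signal of 395.5 ± 86.8 in black and 177 ± 93.8 in agouti mice (1.31 ± 0.17, adjusted p = 3.8e-09). Gm4737 (ENSMUSG00000048087, chromosome 16, 46152985 to 46155077) had a signal of 10.9 ± 4.16 in black and 198 ± 98.5 in agouti mice (-4.08 ± 0.26, adjusted p = 5.9e-32). Ahcy shared 66.0% of its sequence words with Gm4737 and Gm4737 90.4% with Ahcy, so both values are uncertain. limma called 13 genes (5 higher and 8 lower in black mice), 6 of them at least 1.5-fold. Higher were also Pigu (0.23 ± 0.039), Snhg17 (0.40 ± 0.087), Cdk5rap1 (0.36 ± 0.08) and Orai3 (0.16 ± 0.036). Lower were Phf20 (-0.46 ± 0.046), Myh7b (-0.88 ± 0.13), Fam92a (-0.63 ± 0.13), Rgs1 (-0.77 ± 0.16) and Pdzd2 (-0.30 ± 0.068), and, outside the naming rule and named once its value was seen, Itch (-0.21 ± 0.050), with 1 gene without a symbol. In G11L1 mice alone 7 genes were called and in G11L2 mice alone 2. Snhg17, Cdk5rap1, Orai3, Fam92a and Pdzd2 passed in neither label, and Ahcy, Pigu, Myh7b and Rgs1 not in G11L2 mice. Orai3 also lost its call after median-of-ratios rescaling (adjusted p = 0.0879) and quantile normalization (0.1), without the mice with pancreas transcripts (0.0576) and without the 10 least alike mice (0.0858). Cdk5rap1 lost it without either set of mice (0.122 and 0.111), Fam92a with rank-based normal scores (0.0803) and Rgs1 with 10 times the pseudocount (0.0691).

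White coats (25 mice) against pigmented ones gave 2 calls with limma, against 843 genes at an unadjusted p under 0.05. They were Gm4737 (1.75 ± 0.29, adjusted p = 8.47e-05) and Ahcy (-0.91 ± 0.19, adjusted p = 0.0219), the pair named for black coats. The contrast set white against the mean of agouti and black. Means in white mice were 182 ± 135 for Ahcy and 191 ± 125 for Gm4737, close to those of agouti mice. Neither gene was called in G11L2 mice alone or with rank-based normal scores, and Ahcy was not without the 10 least alike mice (adjusted p = 0.139). Prcp (-0.34 ± 0.076, adjusted p = 0.0815) came next without passing.

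Spread between mice of a group also differed. By diet, limma called 325 genes, 272 more variable and 53 less variable on the high fat diet. Gpnmb (1.00 ± 0.13, adjusted p = 7.14e-10), Rbm24 (0.65 ± 0.074, adjusted p = 3.95e-12), Gprc5b (0.95 ± 0.13), Ephb2 (0.72 ± 0.096), Ubd (0.56 ± 0.084) and Trem2 (0.51 ± 0.076) had a larger mean absolute log2 deviation. Less variable were Prom2 (-0.69 ± 0.15), Usp2 (-0.53 ± 0.12), Gm15375 (-0.44 ± 0.066), Col25a1 (-0.40 ± 0.077), Ndrg1 (-0.28 ± 0.05) and 1810055G02Rik (-0.23 ± 0.05). Of the 325 genes 288 were also called for their mean and 156 had the higher mean where the spread was higher, while 98 had a mean under 10 pseudocounts in the less variable arm, where values pile up at the pseudocount. With rank-based normal scores 23 genes were called, and of the genes named here only Rbm24, Col25a1 and Ndrg1 kept the call. With the pseudocount 10 times smaller Ephb2, Ubd, Trem2, Prom2, Gm15375 and Col25a1 lost it (adjusted p from 0.0527 to 0.399). Within G11L1 and G11L2 mice 39 and 29 genes were called, and Prom2, Usp2, Col25a1, Ndrg1 and 1810055G02Rik passed in neither.

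By sex, 715 genes differed in spread, 624 more variable and 91 less variable in males. Moxd1 (2.84 ± 0.22, adjusted p = 8.93e-25), Kcnk1 (1.33 ± 0.11), the pseudogene Gtpbp4-ps1 (1.33 ± 0.096), Cyp2c66 (0.94 ± 0.074), the calcitonin receptor gene Calcr (0.82 ± 0.056, adjusted p = 5.74e-30) and Hcrtr2 (0.71 ± 0.054) were more variable in males. Less variable were Rpap3-ps2 (-1.46 ± 0.15), Fam19a2 (-1.18 ± 0.13), Pla2g4f (-0.88 ± 0.095), Cyp2d9 (-0.80 ± 0.092) and Sult2a-ps1 (-0.67 ± 0.046). Of the 715 genes 596 were also called for their mean and 441 had the higher mean where the spread was higher, while 238 had a mean under 10 pseudocounts in the less variable arm. With rank-based normal scores 152 genes were called, among which Moxd1, Kcnk1, Pla2g4f and Cyp2d9 were not, and 192 and 192 within the 2 generation labels.

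Within groups, single genes varied between mice far more than most. Among 10867 genes with a mean of at least 10 pseudocounts the residual SD was 0.26 (median, log2), with 0.17 and 0.65 at the 10th and 90th percentiles, and 516 genes exceeded 1. Mup19 had the largest residual SD (6.08), with a signal of 0 to 11556 (median 4.57) and 59 mice below the pseudocount, and 100% of its words were shared with other genes. The next were the ribosomal protein and other pseudogenes Rps2-ps13 (4.11), Gm9843 (4.10), Gm10275 (3.92), Gm12918 (3.83), Gm10222 (3.83), Gm10243 (3.57), Gm9385 (3.46) and Rps6-ps4 (3.401), and the haemoglobin gene Hba-a1 (3.56). Each shared over 50% of its words with another gene, from 72.3% for Hba-a1 and 88.2% for Gm9385 to 100% for Gm10222, whose nearest gene was the mitochondrial mt-Nd4l.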

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

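In this part the fit without the 10 least alike mice was chosen after the results were seen. The results below stand out because the diet effect differed between 98 females and 94 males by limma's interaction test. The rule named 53 genes for sex, diet or the interaction, of which 17 passed, 9 with an effect more positive in males. As 12 of the 17 were named because they passed, this count is no test of how common such genes are. Those reported here are given as the effect in males minus that in females (log2), with the effects in females and in males in that order in parentheses.

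The difference was 3.58 ± 0.53 for Sult1e1 (-0.78 and 2.80, adjusted p = 2.35e-07), 2.49 ± 0.51 for Sult5a1 (-3.38 and -0.89, adjusted p = 0.000469), 2.22 ± 0.58 for Sult2a7 (-2.51 and -0.30, adjusted p = 0.00743) and 2.21 ± 0.49 for A1bg (-2.20 and 0.013, adjusted p = 0.00124). It was 1.91 ± 0.28 for Ptgds (-2.22 and -0.31, adjusted p = 2.35e-07), 1.34 ± 0.44 for Mup1 (-1.83 and -0.49, adjusted p = 0.0376), 1.28 ± 0.35 for Cyp3a44 (-1.84 and -0.56, adjusted p = 0.0101) and 0.89 ± 0.28 for Cyp3a41a (-1.001 and -0.11, adjusted p = 0.0314). For each the effect in females was negative, though it did not pass limma's test for Sult1e1 (adjusted p = 0.0922). With the opposite sign it was -1.02 ± 0.35 for Mogat1 (2.66 and 1.64, adjusted p = 0.0456), -1.43 ± 0.32 for Cyp2d9 (1.09 and -0.34, adjusted p = 0.00118), -1.63 ± 0.49 for Acpp (1.91 and 0.28, adjusted p = 0.0219) and -1.75 ± 0.39 for Gprc5b (2.81 and 1.06, adjusted p = 0.00115). It was -1.83 ± 0.54 for Obp2a (0.14 and -1.69, adjusted p = 0.0176), -2.12 ± 0.27 for Csad (0.091 and -2.03, adjusted p = 1.22e-09), -2.41 ± 0.34 for Slc39a5 (2.77 and 0.36, adjusted p = 7.4e-08) and -2.43 ± 0.28 for Cyp3a11 (1.43 and -0.995, adjusted p = 2.67e-11). Only for Cyp3a11 did effects of opposite signs pass the test in both sexes. As Obp2a lay under the pseudocount in females, its interaction cannot be read as a response of males alone.

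In all, 1223 genes had an interaction with the deposited scaling. Of 100 splits of the mice into groups of the same sizes, only 1, the real one, gave as many. The highest other gave 4. These splits shuffled diet within sex and generation label, which removes every effect of diet and not the interaction alone. A count as large thus did not come up where diet had no effect. How many calls arise where diet acts alike in both sexes cannot be read from these splits. The number was 546 in G11L1 mice and 54 in G11L2 mice, groups of 97 and 95 mice, and 617 after median-of-ratios rescaling. Why the generation labels differ in it was not tested.

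The list of female-biased genes passed the set test for the interaction (adjusted p = 0.0359 with an estimated correlation). Of 100 splits, 8 gave at least 1 list past the test, with a highest other count of 2, so chance could not be excluded for the real count of 1 list. Without the 10 least alike mice the adjusted p was 0.0501, and it ranged from 1.01e-11 to 0.588 over its alternatives.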

How the results depend on the processing

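The fits without mice with pancreas transcripts, the 10 least alike mice or the female lacking Xist were chosen after seeing the data. The results covered are the 13 counts, the genes named and the list tests for sex and diet, plus 2 lists for the interaction. Other list members and interaction lists were left out after their reversals had been seen. Of 210 recomputed counts, 161 stayed within 1.5 times the value reported. Of the named genes, 5377 recomputed tests kept direction and side of the threshold, 137 lost the call, 5 gained one and 5 changed sign. Of the list tests these numbers were 1127, 5, 76 and 45. Most lost gene calls came from single generation labels (36 in G11L1 and 40 in G11L2), where fewer mice were tested.

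Counts that moved more are given by setting. Except for the fold limit and for camera's preset correlation, which only replaced the estimated one, the cause was not tested. With 10 times the pseudocount 576 genes differed in spread by diet and 1092 by sex, with it 10 times smaller 185 by diet, and without a filter 1205 by sex. Median-of-ratios rescaling gave 617 interaction genes, 262 generation genes, 4 diet lists and 0 interaction lists. Quantile normalization gave 4906 diet genes in males, 633 interaction genes, 254 generation genes and 0 interaction lists. Array weights gave 344 generation genes, 30 for black coats and 205 for spread by diet. Rank-based normal scores gave 0 for white coats, 23 and 152 for spread by diet and sex, and 0 interaction lists. G11L1 mice alone gave 2348 diet genes in females, 546 interaction genes, 7 for black coats, and 39 and 192 for spread by diet and sex. G11L2 mice alone gave 2432 and 4930 diet genes in females and males, 54 interaction genes, 0 for white and 2 for black coats, 29 and 192 for spread, 4 diet lists and 0 interaction lists. Without the 10 least alike mice 0 interaction lists passed. Camera with its preset correlation called 15 lists for sex, 18 for diet and 17 for the interaction, and fry 22, 23 and 8. A fold of at least 1.5 left 1074 genes for sex, 4.2e+02 for diet (231 higher and 193 lower), 473 and 538 for diet in females and males, 188 for the interaction, 8 for generation, 6 for black coats, and 14 and 98 for spread by diet and sex.

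Quantile normalization turned the sign of Apob (-0.26) and Fgg (-0.054) for sex, and of Ndufa9 (0.011), Atp5b (0.108) and Uqcrc2 (0.049) for diet. Lists whose set test changed direction had not passed with the deposited scaling, and their adjusted p-values under the alternative follow. Fry aside, the cause was not tested. For sex these were, under fry, urea cycle 0.552, acute phase 0.0827, erythroid 0.947, fibrosis 0.552, bile duct 0.569, pancreas 0.511, clock 0.0222, cell cycle 0.552 and periportal 0.216, of which clock genes passed. After median-of-ratios rescaling they were acute phase 0.992, pancreas 0.992 and oxidative phosphorylation 0.997, and after quantile normalization pancreas 0.932, cell cycle 0.932 and oxidative phosphorylation 0.932. In G11L2 mice they were NRF2 targets 1, acute phase 0.959 and oxidative phosphorylation 1, without a filter acute phase 0.978 and periportal 0.978, and with the filter at 10 pseudocounts NRF2 targets 0.984. For diet these were, under fry, female-biased genes 0.744, lipoproteins 0.744, acute phase 0.0617, pancreas 0.389 and clock 0.0738. Median-of-ratios rescaling gave acute phase 0.848, pancreas 0.838 and oxidative phosphorylation 0.756, and quantile normalization gluconeogenesis 0.937, T, NK and B cells 0.937, pancreas 0.903 and oxidative phosphorylation 0.249. G11L1 mice gave xenobiotic 0.961 and oxidative phosphorylation 0.941, G11L2 mice urinary proteins 0.934, acute phase 0.873 and pancreas 0.934, no filter acute phase 0.927 and pancreas 0.984, and the filter at 10 pseudocounts urinary proteins 0.901, gluconeogenesis 0.92, xenobiotic 0.901 and oxidative phosphorylation 0.901. Lists that gained a call under other scalings or filters were lipoproteins (0.0142) and insulin and growth hormone signalling (0.0352) for sex after quantile normalization, and T, NK and B cells for sex without a filter (0.0411). For diet they were cholesterol after median-of-ratios rescaling (0.029) and without a filter (0.0318), periportal genes after that rescaling (0.029) and fibrosis with the filter at 10 pseudocounts (0.0491), and in G11L2 mice cholesterol and fibrosis (0.0475 each).

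A female and a male that share a mouse number were weakly alike. Over 92 such pairs the mean correlation of residuals was 0.0170 against -0.00466 for other numbers (permutation test with 10000 reshuffles within diet and generation label, chosen after the result was seen, one-sided p = 0.0085), and 9 pairs exceeded 0.1. Of the females 6 correlated best with their own number, with 4 expected. The number was not used as a block in the fits reported. With the number as a replicate block 9947 genes (6536 higher in males) and 4 lists were called for sex, and the acute phase list changed direction (adjusted p = 0.987).

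More genes were called lower than higher on the high fat diet, and more higher than lower in males, for which no such test was run. For diet, a single scaling offset common to all genes was tested over 4 classes of mean value with 2717 genes each, where the median diet change was -0.04, -0.09, -0.10 and -0.12. Its range of 0.0785 was wider than the prediction for such an offset allowed. An offset shifts every class alike and leaves this range as it is, so the range cannot decide what caused the excess of lower calls. After median-of-ratios rescaling the medians were 0.034, -0.0096, -0.025 and -0.041, and the higher share of diet calls moved from 26.3% to 52.1%. An offset as a part or the whole of the cause stays open. That prediction was written after the rescaled counts were known, and an earlier test on those counts was set aside because the rescaling itself centres the genes. Which scaling is right cannot be settled from these values, and depth limits low genes most, for which the pseudocount shrinks changes.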

Other observations

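The tests of Ahcy and Gm4737, of the mouse without Xist and of the pancreas transcripts were chosen only after the results were seen. The test of the sex score was written before its own result, after the results for sex, diet and interaction were known.

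Of 100 splits of the mice into groups of the same sizes, 1, the real one, gave as many calls as observed. This held for sex (9998 genes, highest other 2), diet (8310, highest other 2), diet in females (4860, highest other 54) and diet in males (7479, highest other 130). The same held for generation (137, highest other 3), spread by diet (325, highest other 7), spread by sex (715, highest other 1) and lists for sex (4, highest other 1). Chance can be excluded for these. For lists by diet 2 of 100 splits, the real one included, gave 2 lists or more (highest other 2), so chance is unlikely there but not excluded. For black coats 2 of 100 splits gave 13 genes or more, and for white coats 3 of 100 gave 2 or more. There the highest other splits called 223 and 29 genes, many more than the real ones, and what sets those splits apart was not tested.

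In black mice Ahcy was higher and Gm4737 lower than in agouti mice. Reads shared between these genes may account for the opposite shifts: the log2 sum of both had a residual SD of 0.370, against 0.957 for Ahcy and 1.92 for Gm4737, and differed between black and agouti mice by 0.07 ± 0.077. The log2 sum of 2 genes of similar level can vary less than each gene without shared reads, so the lower SD alone cannot decide it. A variant linked to the nonagouti gene (chromosome 2, 154791402 to 155051012) could set which gene the reads are given to, and of the 13 genes called for black coats 7, Ahcy included, lie within 10 Mb of it. As the coats themselves differ at that gene, calls near it are expected either way, so this does not decide it. Founder genotypes and reads were not analysed here, so a change in Ahcy transcription itself stays open, as does a biological role of coat colour.

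In 1 chow female of the G11L2 label Xist had a signal of 0.361, against at least 88.2 in the 97 other females and 0.332 to 2.47 in males. A male under a female label is argued against: 16 of the 24 female-biased list genes lay above every male in this mouse, as did 7 to 20 (median 15) in other females. A single X chromosome in place of 2 may account for it: the mean log2 value of Kdm6a, Kdm5c and Eif2s3x was 3.35, at or below which lay 1 of the 97 other females (mean 3.89 ± 0.15, males 3.503 ± 0.18). A first test, whether each of these genes lay in the range of males, was replaced because the ranges of the sexes overlap, and this mean leaves out Ddx3x, which at 50.2 had 11 of the 97 other females at or below it. Loss of Xist with both X chromosomes kept, which needs these genes at or above the level of other females, is argued against: the mean over all 4 lay at -2.83 SD from that of other females, with 2 of the 97 at or below it.

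A hypothesis was that the high fat diet narrows the sex difference. A score (mean log2 value of 183 female-biased minus 230 male-biased genes chosen in G11L1 mice) was compared in G11L2 mice. It was higher by 0.194 in 21 high fat than in 25 chow males (95% interval -0.200 to 0.587, permutation test with 100000 resamples, two-sided p = 0.321, adjusted p = 0.321), and by 0.195 in 24 high fat than in 25 chow females (-0.088 to 0.479, p = 0.177, adjusted p = 0.321). With any 1 mouse left out the differences ranged from 0.102 to 0.261 in males and from 0.137 to 0.288 in females. A rise in males or a drop in females would narrow it, and each had a prediction of its own. Both predictions had counted a missed p against it, and this was changed after the result because a missed p excludes nothing: the intervals leave both directions open. The gap between the sexes was 4.29 on either diet in these G11L2 mice. The G11L1 mice, in which the genes were chosen, were not tested. Their male scores ran from -3.19 to -1.40 on chow and from -3.35 to 0.514 on the high fat diet, so the gap of 4.29 speaks for G11L2 mice alone.

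In 11 mice (5 of them female, 10 of the label G11L2) the mean signal of the 9 tested pancreas genes was above 1, and the 3 mice highest for Ctrb1 were among the 11 highest for 100% of the other 8 members. The highest values were in 1 chow male, with Amy2a5 at 247, Ctrb1 at 197 and Pnlip at 143, while medians over all mice lay between 0 and 0.05 for each member. Without these 11 mice 9882 genes were called for sex, 8315 for diet and 1472 for the interaction. Without the 10 mice least alike the others (median correlation with the rest from 0.925 to 0.953 over all mice) these counts were 10001, 8168 and 1181, and without the female lacking Xist 9970, 8319 and 1182.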
